A study of Pimephales promelas with 12 samples.

How the data were processed

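RNA from the liver and brain of female fathead minnows (Pimephales promelas) was measured on 12 Agilent two-colour arrays, 3 for each tissue and treatment. Per the labels, the fish had spent 7 days in control water or in water with 60 ug/L fadrozole, an inhibitor of aromatase, the enzyme that makes estrogens from androgens. Each array held RNA pooled from 2 fish, and the same 6 pools of fish gave both tissues, so the pool is the biological replicate. The series design text says that the third control pool joined fish of different tanks. The sample was labelled with Cy5 and hybridized beside a Cy3 common reference made from liver, brain and gonad of both sexes. No dye was swapped.

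Per the file headers, Agilent Feature Extraction gave for each spot a mean intensity and a local background intensity in each channel, with flags for outlier spots, saturation and signals well above background. The same deposited files hold intensity values after background subtraction and LOWESS dye normalization by the scanner software, and their log10 ratio of sample over reference, per the file headers. The series matrix deposited by the authors holds the same log10 ratio, which lay within 0.005 of the scanner value for every spot. Software version A.7.5.1 read 10 arrays and version 8.1.1.1 read brain control 2 and brain fadrozole 3. Each array had 10806 spots, of which 10262 carried 5131 probes on 2 spots each. The probe names in the files gave 248 probes a gene name, covering 99 names, and left 4883 probes as unnamed clones and contigs, while 34 named probes are marked as reverse complements. The files give no genome position, and no probe was named from any other source.

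From the raw intensities, background was corrected with normexp at an offset of 50, and log2 ratios of Cy5 over Cy3 were computed and normalized by loess within each array, with control spots given no weight. Spots flagged as outliers in either channel were left out, and the remaining spots of a probe were averaged. A probe was tested if its Cy5 signal was well above background on at least 3 arrays of the comparison (of each tissue for the difference between tissues). Linear models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. For lists of genes fixed before the data were examined, the count adjusted over the list alone is given beside that over all probes. The former is not adjusted across lists. Python 3.11.15 drew the plots with matplotlib 3.10.9.

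The comparisons were fadrozole against control within liver and within brain, the difference between these effects over all 12 arrays, and liver against brain in control fish. These, the alternatives described as planned, the 32 gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each fadrozole comparison, up to 10 named genes per direction that passed and separated the groups on every array. With fewer than 5 passing probes it took the 10 named genes with the smallest p per direction, said not to pass. It added up to 4 members of each list with a passing member, 9 genes of reproduction, steroid response or reference use whatever their values, and the 5 largest named differences each way between the tissues. For a gene with several probes the brightest is given, except where a rule on p chose another. Of the 32 lists, 18 had a measured member and none had the 5 measured genes that the planned camera test needed, so that test could be run on 0 lists. Camera, with its preset correlation of 0.01 and with an estimated one, and fry were therefore run with every probe of a listed gene counted.

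A single library, labelled liver control 2, did not resemble the other liver arrays. Liver comparisons and those between tissues are given with it, as planned, and without it. Leaving out each array was planned, but giving every value of the fit without this library was a choice made after seeing the data. Without it control liver has 2 arrays. For pairing, deviations from the group means were correlated between arrays of the same number. Liver and brain with the same number come from the same fish, which pairs them by design, although their correlations were -0.21, -0.38 and -0.36 in control fish and 0.10, 0.13 and 0.03 in fadrozole fish. The fit with the fish pool as a block is given beside those comparisons. Control and fadrozole pools share only a number. The description of brain fadrozole 3 carries a sample code that departs from the pattern of the others, and it was kept in the group of its title.

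The days on which the images were extracted fell into 3 sessions, used as a stand-in for batches. Session 1 held brain control 1, liver control 1 and 3, and liver fadrozole 2 and 3. Session 2 held brain control 3, brain fadrozole 1 and 2, the library labelled liver control 2 and liver fadrozole 1, and session 3 held brain control 2 and brain fadrozole 3.

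The alternatives were no background subtraction, the scanner's processed signals, the series matrix, median centring in place of loess, Aquantile between arrays, Cy5 alone, looser and stricter filters on dim probes, flagged spots kept, an intensity trend with robust variances, each array left out in turn, and blocks for session and replicate number. Tested on simulated data with 200 changed probes, the liver fit recovered 19.4% of changes of 1 log2 unit and 65.7% of changes of 2 units. The liver fit without the library labelled liver control 2 recovered 59.7% and 92.5%, and the brain fit 80.6% and 92.5%. The simulated noise was normal, independent between probes and equally wide on every array, with 200 probes truly changed. These shares are therefore not the power of the real fits. The real brain fit did not call aromatase at -1.80 (limma, adjusted p = 0.65). With 3 arrays a group, an exact two-sided permutation test cannot go below p = 0.1, so single genes were tested only with limma. The number of arrays and the brightness of each array limit the precision, and where spots were at the scanner's ceiling the size of a difference is not known.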

Results

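The data were log2 ratios of sample over common reference for 5131 probes in 12 arrays, 3 each of control liver, fadrozole liver, control brain and fadrozole brain. The number of probes well above background in the sample channel ran from 2131 on brain control 2 to 4817 on liver fadrozole 3, and was between 3644 and 4712 on the other brain arrays. The correlation between the spots of a probe was 0.977 to 0.993 within an array. Brain arrays correlated with each other at 0.903 to 0.983 across probes. Liver arrays other than the library labelled liver control 2 correlated with each other at 0.737 to 0.974, and with the brain arrays at 0.149 to 0.288.

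The library labelled liver control 2 went against its label. It correlated at 0.239 to 0.296 with the other liver arrays and at 0.693 to 0.80 with the brain arrays. Some transcripts that liver secretes were far below their levels on the other control livers. Vitellogenin precursor, the egg yolk protein precursor, was at -4.67 against 2.84 and 2.11 on liver control 1 and 3. Retinol binding protein 4, the plasma carrier of vitamin A, was at -4.86 against 0.90 on both other control livers, and transferrin, the plasma iron carrier, at -5.53 against -1.76 and -0.09. Transcripts typical of brain were not at brain levels either, as aromatase (probe EA_Pp_10086, the brighter over all arrays) was at -1.84 against 3.71 to 3.92 in control brain. Alpha amylase, in contrast, was at 4.18, near its 4.22 to 5.04 on the other livers and far from its -2.14 to -0.57 in brain.

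**Figure D1:**
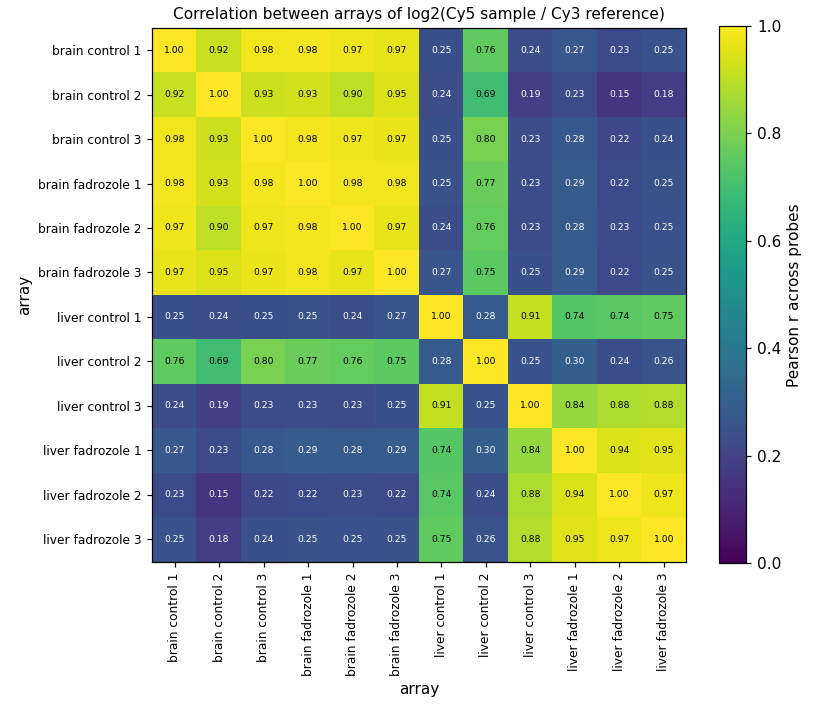
Pearson correlation across probes of the log2 sample over reference ratios between each pair of the 12 arrays, with arrays on both axes. The library labelled liver control 2 lies at 0.239 to 0.296 with the other liver arrays and at 0.693 to 0.80 with the brain arrays.

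**Figure D2:**
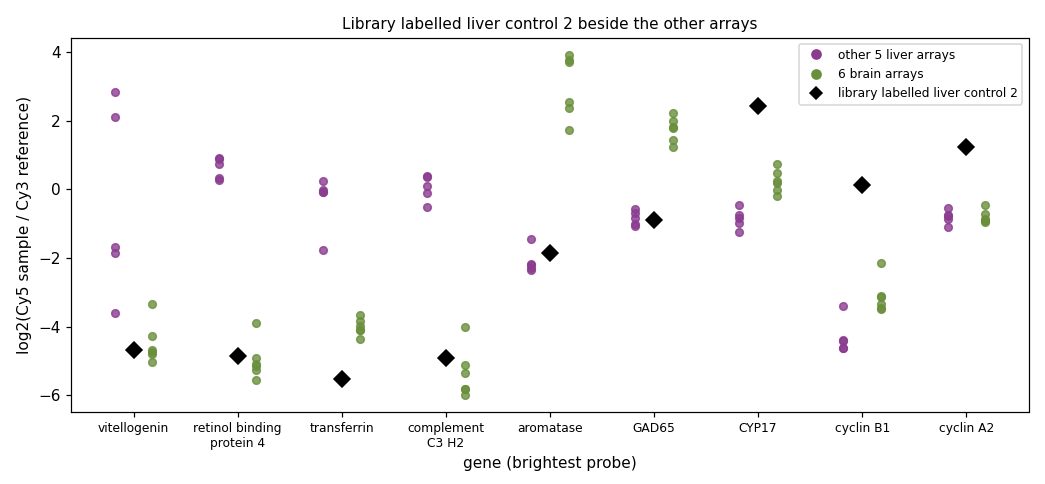
Log2 sample over reference ratio of 9 genes on each array, with the genes on the horizontal axis, the other liver arrays and the brain arrays as circles and the library labelled liver control 2 as diamonds. CYP17 is at 2.42 on that library and at most 0.74 elsewhere.

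The first comparison asked what an aromatase inhibitor did to transcripts of the female liver, the organ that makes egg yolk protein. Against liver control 1 and 3, vitellogenin precursor fell by 4.86 on the log2 scale (SE 0.67, limma, adjusted p = 0.035), from 2.47 ± 0.51 (SD, n = 2) to -2.38 ± 1.07 (SD, n = 3), with all 3 fadrozole arrays below both controls. Its second probe fell by 6.77. The first probe was saturated on both controls, so the size of its fall is not known exactly, and in the Cy5 channel alone it differed by -2.64 (adjusted p = 0.11). Reticulocalbin 3, a calcium-binding protein of the secretory pathway, fell by 1.51 (SE 0.12, adjusted p = 0.0083), from 3.76 ± 0.03 (SD, n = 2) to 2.25 ± 0.07 (SD, n = 3), and its second probe by 1.64. Under median centring the first probe was at -0.544 (limma, adjusted p = 0.48). With Cy5 alone, the series matrix and the scanner's processed signals it was at -1.288 to -1.175 and did not pass (limma, adjusted p = 0.054 to 0.062). As the comparison of tissues gives, a probe of this gene was saturated on 1 of these controls, so the size of the fall may not be exact. One probe of CD18 type 2, an integrin chain of leukocytes, fell by 0.84 (adjusted p = 0.034), while its other probe differed by 0.30. Without liver control 1 as well, vitellogenin differed by -4.50 (adjusted p = 0.15) and CD18 type 2 no longer passed, and without liver fadrozole 2 or 3 none of these 3 genes passed (vitellogenin -5.12 and -5.21, adjusted p = 0.11 and 0.091; reticulocalbin 3 adjusted p = 0.073 and 0.063). CD18 type 2 also did not pass without liver fadrozole 1, where vitellogenin was at -4.24 (adjusted p = 0.021). With the session as a block vitellogenin was also at -4.24, but liver fadrozole 1 is then alone in its session. That block in effect repeats the fit without liver fadrozole 1 and is no separate check.

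In that comparison 143 of 4555 probes passed, 29 higher and 114 lower with fadrozole, and 840 had an unadjusted p under 0.05. Of the 114 that fell, 109 had no gene name, 58 fell by more than 4 log2 units and the median change of the 114 was -4.05. Most tested probes had no gene name either, as 217 of the 4555 had one. Of the 29 that rose, all without a gene name, 0 rose by more than 4 units and the median was 1.49. The count was 59 without liver control 1, 1060 without liver control 3 (435 higher and 625 lower), and 70, 42 and 31 without liver fadrozole 1, 2 and 3. With the session as a block, which in effect leaves out liver fadrozole 1, it was 70, and under median centring 58. With the library labelled liver control 2 among the controls, as planned, limma called 0 of 4663 probes, with 612 at an unadjusted p under 0.05 and a smallest adjusted p of 0.14. Taken from 1 fit over all 12 arrays the count was 165, of which 104 were higher and 61 lower. In the planned fit of the 6 liver arrays vitellogenin differed by -2.48 (SE 2.15, adjusted p = 0.53), with control liver at 0.09 ± 4.14 (SD, n = 3). All 3 fadrozole arrays lay on one side of all 3 controls for 1306 of 4656 probes, or 28.0%, where chance gives 10% on average. Probes are not independent and the share was not counted for other splits, so its excess over 10% was not tested.

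**Figure D3:**
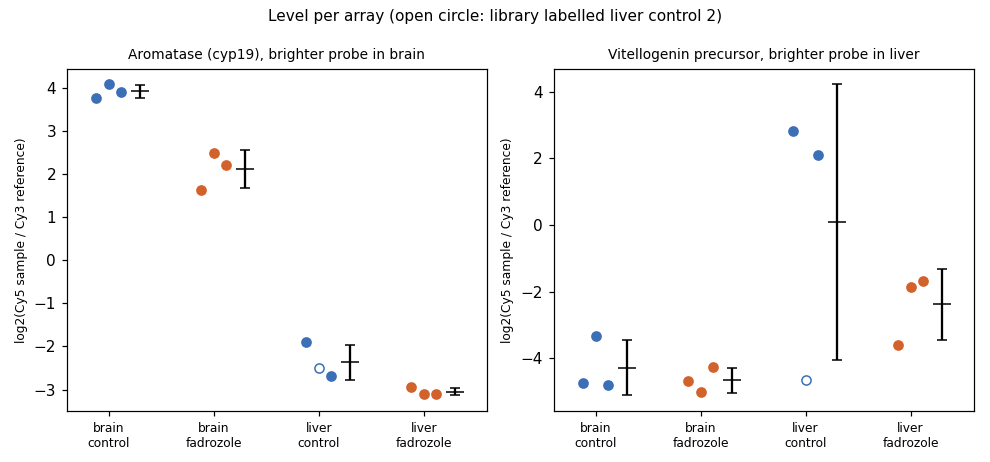
Log2 sample over reference ratio of 1 probe each of aromatase and vitellogenin precursor on every array (circles), with the mean and SD of each group of 3 arrays (bars), and the library labelled liver control 2 as an open circle. Aromatase in fadrozole brain is at 2.11 ± 0.44 against 3.91 ± 0.16 in control brain, and vitellogenin in liver fell by 4.86 when that library is left out.

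Among the genes of estrogen signalling in liver, given here without the library labelled liver control 2, none but vitellogenin passed. Estrogen receptor alpha, which drives vitellogenin transcription, differed by -0.90 (SE 0.34, adjusted p = 0.27) and its second probe by -0.48. Estrogen receptor beta differed by -0.28, androgen receptor by 0.14, aromatase by -0.45, CYP1A, an enzyme of foreign compound metabolism, by -0.28, and zona pellucida glycoprotein 3, an egg coat protein, by 0.47 (SE 0.76). Adjusted over the list alone, 1 of the 9 genes chosen in advance passed, vitellogenin (adjusted p = 0.0078). The reference genes elongation factor 1 alpha and beta actin differed by -0.75 and 0.47. Adjusted over these 2 genes alone, elongation factor 1 alpha passed (limma, adjusted p = 0.024). It did not pass among the 9 genes (0.055) or over all probes (0.15). Under median centring its difference was 0.15 instead, and that of aromatase 0.03. Estrogen receptor beta was at 0.09 without liver control 1 as well, and zona pellucida glycoprotein 3 at -0.10 without liver fadrozole 2, so the directions of these 4 genes are not settled. Without liver control 1 as well, CYP1A was at -0.03, aromatase at -0.07 and beta actin at 0.15.

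No gene group in liver had a difference that passed over all probes in the planned fit. There, cytochrome c oxidase subunit III (-0.93) and subunit II (-0.75), mitochondrial subunits of the respiratory chain, passed adjusted over the list alone (smallest adjusted p = 0.028), as 2 of 3 measured members. The probe of subunit III was saturated on all 3 fadrozole arrays and on 2 controls, and that of subunit II on 1 fadrozole array, so these differences are not known exactly. Hexokinase I (0.47) and lactate dehydrogenase A (-0.68), at the start and end of glycolysis, passed in the same way (smallest adjusted p = 0.037), as did elongation factor 1 alpha (0.013), and 0 other lists had such a member. These limma p-values were adjusted within each list and not across the 18 lists with a measured gene. With that many lists some such passes can arise by chance. The hexokinase I probe is marked as a reverse complement, and the 3 others of that gene differed by -0.28 to -0.01. Without the library labelled liver control 2 the lists with 1 such member were the egg proteins (0.0017), the apolipoproteins (0.020), through a probe saturated on all 5 arrays, and the reference genes. The remaining genes that the rule named in the planned fit were at -1.58 for heat shock protein 90 beta, -1.54 for NADH ubiquinone oxidoreductase subunit 4, -0.94 for elongation factor 1 gamma, -0.88 for 28S, -0.83 for Rap 1B, -0.80 for Zn Cu superoxide dismutase and -0.73 for CD18 type 2. On the other side were complement C3 H1 (2.29), selenoprotein (1.51), trypstatin (1.14), angiogenin related protein (1.07), the Na K ATPase alpha subunit 3 (0.78), MAP kinase (0.43), glucose 6 phosphate 1 dehydrogenase (0.39), myosin light chain 2 (0.36) and polyA polymerase (0.29). The selenoprotein probe is marked as a reverse complement. Without the library labelled liver control 2 complement C3 H1 was at 1.51, selenoprotein at 0.91, trypstatin at 0.94, the Na K ATPase subunit at 0.53, MAP kinase at 0.32 and glucose 6 phosphate 1 dehydrogenase at 0.24. In the planned fit median centring turned the direction of 28S, CD18 type 2, cytochrome c oxidase subunit II, both elongation factors, superoxide dismutase, beta actin, aromatase and CYP1A.

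With every probe of a listed gene counted, camera with its preset correlation called 4 of 11 lists in the planned liver fit, but 0 with an estimated correlation (smallest adjusted p = 0.65). The calls were hepatocyte genes higher (adjusted p = 0.0099), oxidative phosphorylation lower (0.014), apolipoproteins higher (0.043) and complement higher (0.043). The library labelled liver control 2 held the hepatocyte genes retinol binding protein 4 and transferrin far below the other controls, as given above. In the same order, the rotation test fry of limma, which asks whether the genes of a list move one way on balance, gave unadjusted p-values of 0.088, 0.053, 0.052 and 0.23. Without that library 1 list was called, the apolipoproteins higher (adjusted p = 0.0058 preset, adjusted p = 0.935 with an estimated correlation; fry p = 0.017). Its members apolipoprotein A 14 kDa variant and apolipoprotein Eb, lipid carriers of plasma, differed by 0.49 and 0.09. Neither passed over all probes. The first was saturated on all 5 arrays, so its difference and its pass adjusted over the list alone are not read as a change. The probe of the second is marked as a reverse complement.

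The second comparison asked the same of the brain, which in fish has high aromatase activity. Aromatase had the smallest p and the largest difference of the named genes tested in brain, at 2.11 ± 0.44 (SD, n = 3) with fadrozole against 3.91 ± 0.16 (SD, n = 3) in control brain, a difference of -1.80 (SE 0.24) or 3.48-fold. These values are of probe EA_Pp_10085, the brighter in brain. All 3 fadrozole arrays were below all 3 controls, and the second aromatase probe, EA_Pp_10086, differed by -1.59. Over all 4210 probes limma did not call it (adjusted p = 0.65). Adjusted over the list alone it passed among the 9 genes chosen in advance (adjusted p = 0.0028) and in the steroidogenesis list of 2 measured genes (0.00061). Within session 2 the difference was -1.83 and within session 3 -1.86, and with the session as a block it was -1.85 (SE 0.31). Without brain fadrozole 3, whose description carries an unlike code, it was also -1.85.

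No brain probe passed: limma called 0 of 4210, with 125 at an unadjusted p under 0.05, 48 higher and 77 lower. The groups did not overlap for 349 of 4207 probes, or 8.30%, where chance gives 10% on average. This share was not tested either. Delta 6 fatty acyl desaturase, which makes polyunsaturated fatty acids, differed by 0.61 (SE 0.14), with 0.54 on its second probe, and the taurine transporter by 0.81 (SE 0.29), with 0.32 on its second probe. GAD65, the glutamic acid decarboxylase which makes the transmitter GABA, differed by 0.51 on one probe and by -0.01 on the other. Differences on the lower side were -0.91 for apolipoprotein A 14 kDa variant, -0.76 for zona pellucida glycoprotein 3, -0.66 for c mos, -0.63 for Rap1 GTPase activating protein, -0.57 for alpha amylase and -0.51 for alpha 2 plasmin inhibitor. TMPITNFa (-0.41), the p27 like kinase inhibitor (-0.29) and CD18 type 2 (-0.16) were the remaining ones. Many of these depended on 1 array. Without brain control 2, apolipoprotein A 14 kDa variant was at -0.44, c mos at -0.16, alpha amylase at -0.27, alpha 2 plasmin inhibitor at -0.29, TMPITNFa at -0.17 and CD18 type 2 at -0.10. Rap1 GTPase activating protein was at -0.32 without brain fadrozole 2, zona pellucida glycoprotein 3 at -0.37 without brain fadrozole 3, and the p27 like kinase inhibitor at -0.10 without brain control 1. On the higher side were creatine kinase M3 (0.67), myosin light chain 2 (0.52), transferrin (0.28), inhibin beta b (0.25), the peroxisome proliferator activated receptor isoform b (0.22), K ras (0.17) and the Na K ATPase alpha subunit 3 (0.11). Creatine kinase M3 and myosin light chain 2 were high on brain fadrozole 2 alone, at 2.26 and 1.67, and without it differed by 0.01 and -0.09. K ras was at 0.02 without brain fadrozole 3, the peroxisome proliferator activated receptor at 0.14 without brain control 1 and transferrin at 0.17 without brain control 2. The Na K ATPase alpha subunit 3 was at -0.05 with Cy5 alone, so its direction is not settled.

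Of the remaining genes chosen in advance, estrogen receptor alpha differed by 0.08 in brain, estrogen receptor beta by -0.11, androgen receptor by -0.06, CYP1A by -0.08, vitellogenin by -0.37, beta actin by 0.14 and elongation factor 1 alpha by 0.11. None passed, over all probes or adjusted over the list alone. Without brain control 2 vitellogenin differed by 0.11 and estrogen receptor beta by 0.16. Androgen receptor was at 0.02 without brain control 1, beta actin at -0.01 without brain fadrozole 1 and elongation factor 1 alpha at -0.05 without brain control 3. Estrogen receptor alpha was at -0.03 under median centring, so the directions of these 6 genes are not settled. With every probe counted, camera called 0 of 8 lists in brain, the smallest adjusted p being 0.065 for glucose metabolism.

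The third comparison asked whether the tissues responded differently. Vitellogenin did when the library labelled liver control 2 was left out: its response in liver was lower than that in brain by a log2 difference of -4.49 (SE 0.84, limma, adjusted p = 0.022), and of -6.36 on the second probe (adjusted p = 0.0051). In that fit 104 of 4045 probes differed between the tissues, 19 with a higher and 85 with a lower response in liver, and 102 of them had no gene name. The median size of their change was 3.13 in liver and 0.21 in brain. The probes were called on the difference between these changes, so the medians describe the calls and do not test them. With the fish pool as a block as well, 92 probes differed, 14 higher and 78 lower. Without session 3 as well as that library, 103 differed. The balance of directions depended on the arrays and the normalization, as the next paragraph gives.

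With all 12 arrays 4 of 4119 probes differed, none with a gene name, and 442 had an unadjusted p under 0.05. Seen after their values, the clearest were EA_Pp_13985 (2.38 higher in liver, adjusted p = 0.023), EA_Pp_14828 (1.94, 0.023) and EA_Pp_12326 (-2.32, 0.040), and the last differed by 1.47. All 4 were also among the 104. With the fish pool as a block on all 12 arrays limma called 0, with 340 at an unadjusted p under 0.05, and with the session as a block also 0, with 391. Under median centring 11 differed, all with a higher response in liver. The count was 248 without liver control 3, of which 185 were higher and 63 lower in liver, 7 without liver control 1, 1 without liver fadrozole 2, and 0 without any one of the remaining arrays apart from the library labelled liver control 2. Across probes, which are not independent replicates, the changes in liver and brain correlated at r = -0.025 (rho 0.011, 4119 probes), and at r = 0.14 (rho 0.14, 4045 probes) without the library labelled liver control 2.

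The last comparison set control liver against control brain as a baseline and a check of the labels. Aromatase was lower in liver by a log2 difference of -5.63 (SE 0.24, limma, adjusted p = 0.0018), lactate dehydrogenase A, a glycolytic enzyme, by -3.64, cytochrome b, a mitochondrial subunit, by -2.31 and GAD65 by -2.22, and all 4 passed. Alpha amylase, a digestive enzyme, was higher in liver by 5.88 (SE 0.38, adjusted p = 0.0025). Heat shock protein 90 alpha differed by -2.17 (adjusted p = 0.061). Vitellogenin (4.38), reticulocalbin 3 (4.08), retinol binding protein 4 (3.76) and apolipoprotein A 14 kDa variant (3.46) did not pass, with SDs of 3.25 to 4.14 over the control livers. Without the library labelled liver control 2 they were higher in liver by 6.76, 6.28, 5.68 and 5.33, and all passed (adjusted p between 0.0016 and 0.0022). Vitellogenin and apolipoprotein A 14 kDa variant were saturated on both of these control livers, and alpha amylase and the other 2 on 1, so the sizes of these differences are not known exactly.

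Of 4487 probes 211 passed, 31 higher and 180 lower in liver. Without the library labelled liver control 2, 1420 of 4315 passed, 729 higher and 691 lower, among them all 211 in the same direction. With the fish pool as a block 0 passed in limma with all 6 arrays, where 596 had an unadjusted p under 0.05, and 1241 without that library. With the session as a block 0 passed, where 589 had an unadjusted p under 0.05. The count was 95, 122 and 88 without brain control 1, 2 and 3, and 100 and 116 without liver control 1 and 3.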

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

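The tests of session and of a single probe for aromatase and the session test for vitellogenin were chosen after the results were seen; the other tests were written before they were run. Counts without the library labelled liver control 2 were planned, as for each array, while other values without it, and block fits without it, were chosen after seeing the data.

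A difference in response between the tissues was tested with an interaction term. It marked 4 probes with all 12 arrays, and 104 without the library labelled liver control 2, among them the vitellogenin precursor probes EA_Pp_10281 at -4.487 and EA_Pp_10282 at -6.362 (log2, liver minus brain). With the fish pool as a block, as the pools gave both tissues, it marked 0 and 92. Without the block, among the splits of the 6 fish pools into 3 and 3, only 1 of 10, the real one, called as many as 4 probes, and the highest other called 0. With 10 splits no share under 0.05 can be reached, and the same holds for the counts that follow. In liver all 10 of 10 splits called as many as the real 0, with 0 as the highest other, and limma gave 612 at an unadjusted p under 0.05. In brain the figures were also 10 of 10, 0 and 0, with 125 unadjusted. Both shares were fixed in advance, since no split can call fewer than 0 probes. Liver against brain in control fish gave 211 in the real split and 0 as the highest other, so 1 of 10 was as large. Each other split mixed the tissues within both groups, which widens the spread, so its 0 tells little.

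The fall of vitellogenin in liver is the first pattern a biologist may want to follow. A difference between extraction sessions is argued against, since within session 1, with 2 arrays of each group, the difference was -4.243; the only control of session 2 was the library labelled liver control 2, against which it was 1.05. Normalization against the reference channel cannot be the whole cause, since Cy5 alone gave -2.635. How much of the -4.858 of the main fit rests on it was not tested. With Cy5 alone the difference did not pass over all probes (limma, adjusted p = 0.11, and 0.0046 to 0.11 over the alternatives that keep both controls). The named technical explanations thus left a fall in place, though not its size, and its biological cause was not tested. It rests on 2 control arrays, and without liver control 1 it did not pass (-4.50, adjusted p = 0.15).

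For lower aromatase in brain, extraction sessions are argued against as the whole cause, since with the session as a block the difference was -1.846. That value rests on 1 control array in session 2 and 1 in session 3. The session is only a stand-in, so other batches of labelling or hybridization were not tested. Hybridization of other transcripts to a single probe is argued against by the second probe, at -1.595. A biological cause was not tested. Over all probes the difference did not pass in any alternative that was run (adjusted p 0.14 to 1.00).

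For the library labelled liver control 2, noisy spots are argued against, since its spots agreed at 0.9859 and the lowest of the other 5 liver arrays was 0.977. Spot agreement cannot show poor RNA or labelling, which both spots of a probe share. Brain control 2, with 2131 probes well above background, agreed best, at 0.993. The library had 4272 probes well above background, between the 3974 of liver fadrozole 1 and the 4817 of liver fadrozole 3. A swap with a brain array is argued against as well: over the 50 probes highest in control brain its median distance from control brain was -5.287, and all brain arrays correlated at 0.903 or more. RNA of gonad under this label cannot be told apart from other sources. Gonad library clones made up 11.06% of the 235 probes that stood out on it, above the 0% to 4.44% on other arrays with enough such probes but below the 18.1% over all probes, a share that the prediction had not allowed for. No biological explanation was tested, since the design gives none within the control group.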

How the results depend on the processing

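Leaving out each array, the library labelled liver control 2 included, was planned. Settings that leave out session 3, that change a further choice without that library, or that join the block with counting every probe (with a preset or an estimated correlation), were chosen after seeing the data.

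In liver 0 probes were called by limma in the planned fit and in 17 of 19 alternatives (unadjusted 240 to 1134); 1 fit over all 12 arrays called 165 (104 higher, 61 lower), of which 33 were among the 143 (29 higher, 114 lower), and leaving out each array gave 0 to 143, the latter without the library labelled liver control 2. Without that library the 143 became 58 under median centring (43 shared) and 70 with the session as a block (68 shared). The block in effect leaves out liver fadrozole 1, so it is no check apart from leaving out that array. Leaving out a further array gave 31 to 1060 (1060 without liver control 3, 435 higher); a lone control was assumed to vary like the other group. Its other alternatives gave 103 to 173. Vitellogenin passed in 11 of 16 alternatives (-5.22 to -2.64), reticulocalbin 3 in 10 and CD18 type 2 in 6, always lower. In brain 1 probe was called with the scanner's processed signals and 1 with the series matrix, the unnamed EA_Pp_11972 (-4.51 and -4.48), and 2 without session 3; the other 17 gave 0, leaving out each array included. Aromatase was at -1.99 to -1.42 throughout.

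For the difference between tissues, median centring gave 11 (all higher), Cy5 alone 0, the strict filter 0 and the session block 0 (unadjusted 362, 170 and 391). The replicate block of fish pools gave 0, and 92 with the library labelled liver control 2 left out as well. Without it and session 3 it was 103. Leaving out each array gave 0 to 248, with 104 without the library labelled liver control 2 and 248 without liver control 3 (185 higher). For liver against brain, median centring gave 67, Cy5 alone 327, the session block 0 (unadjusted 589) and the replicate block 0, or 1241 with that library left out as well. Leaving out each array gave 88 to 1420, the latter without that library. The correlation of changes was 0.0564 under median centring and 0.0499 with Cy5 alone, and -0.1108 to 0.1356 leaving out each array. Counting every probe gave 4 lists in liver and 0 in brain, and 6 and 1 with the replicate block, but with an estimated correlation 0 in each, with or without the block. Control and fadrozole arrays share only a number (correlations in liver -0.11, -0.06 and 0.21, in brain 0.12, -0.44 and -0.37); this block changed no other call.

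Median centring moved the median of all probes in liver from -0.08 to 0.05, and without the library labelled liver control 2 from -0.05 to 0.15. In the planned fit it reversed 28S (0.197), CD18 type 2 (0.01), Zn Cu superoxide dismutase (0.328), cytochrome c oxidase subunit II (0.169), elongation factor 1 alpha (0.301) and elongation factor 1 gamma (0.161), and elongation factor 1 alpha (0.151) without that library. It also turned beta actin (1.202), aromatase (0.019) and CYP1A (0.202), without that library aromatase (0.032), and in brain CD18 type 2 (0.19), estrogen receptor alpha (-0.03) and vitellogenin (0.104). The cause of these changes was not tested. Of 530, 523, 175 and 188 single gene values in liver, brain, liver without that library and liver against brain, 505, 512, 148 and 154 kept their direction and side of the threshold. Aquantile changes no ratio, so it tests nothing here. Brain control 2, with 2131 probes well above background, limits what dim brain probes can show.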

Other observations

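All tests of this part were chosen after the results were seen.

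Most of the probes that fell in liver without the library labelled liver control 2 had no gene name (109 of 114). Most tested probes had none either, so this share does not show how far the fall went beyond named genes. The 5131 probes on the array hold 4970 distinct sequences, and 5 unnamed probes share the sequence of a named probe. A count of probes is therefore not a count of transcripts. Of the 114 probes that fell, 74 fell by more than 2 log2 units and 20 were saturated on both controls, so the sizes of those changes are not known. Of the 104 probes that differed between the tissues, 90 were also called in liver alone, and 85 were lower there. Both fits use the same liver arrays, so much of this overlap is built in and it is no separate support. Of these 104 the files name only the 2 vitellogenin probes. Whether the unnamed ones hold more yolk protein transcripts was not asked, since the probe sequences were not searched against other sources.

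Some blood plasma and xenobiotic genes showed no difference that passed in liver without that library. Transferrin (0.98), complement C3S (0.28) and complement C3 H2 (0.21) were saturated on all 3 fadrozole arrays and on 1 of the controls, so the sizes of their differences are not known. Alcohol dehydrogenase 3 differed by 0.88 and 0.90 on its probes (adjusted p = 0.16 for the first), and cadherin 17 by 0.47. Fatty acid binding protein 11 (-0.83) and P450 2M1 (-0.64) were high on liver control 1 alone, at 1.95 and 0.15, while liver control 3, at 0.52 and -0.67, lay among the fadrozole arrays. Beta globin and alpha globin, of red blood cells, differed by 0.06 and -0.01, although alpha globin was at -0.26 and -1.29 on the controls. Alpha amylase, a marker of exocrine pancreas, differed by -0.50.

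Liver control 1 and 3 also differed from each other. They correlated at 0.910, and liver control 1 correlated at 0.737 to 0.754 with the fadrozole livers against 0.842 to 0.884 for liver control 3. Of the 235 probes that stood out on the library labelled liver control 2, 83.4% were higher on liver control 1 than on liver control 3, against 63.1% of all probes.

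Of 6 genes taken as markers of gonad, some of whose levels had been seen before they were listed, 3 stood out on the library labelled liver control 2. Cyclin B1 and cyclin A2 among them are cell cycle genes in the fixed lists, so they do not mark gonad alone. CYP17, of androgen synthesis, was at 2.42 (at most 0.74 elsewhere), cyclin B1 at 0.12 (at most -2.14) and cyclin A2 at 1.22 (at most -0.45). Zona pellucida glycoprotein 3 was at -4.82, c mos at -2.18 and inhibin beta b at -0.01, all within the other arrays.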
